A study of Rattus norvegicus with 3 samples.

How the data were processed

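RNA from neonatal rat ventricular myocytes treated with ethanol, or with 100 nM dexamethasone for 1 h or 24 h, was sequenced, with 1 sample per group in the labels. The sample titles speak of 2 libraries per group. Whether these entered the authors' test separately is not given in the sources used here. TopHat, Cufflinks and Cuffdiff and the genome build rn5 are named in the submitters' processing notes, without versions or roles. Per the file headers, which follow Cuffdiff's column layout, the deposited table held 1 FPKM value per gene and group for 17450 rows with 16947 distinct symbols. The scaling of libraries is not given in the sources used here, and depth is unknown. The test statistic, used here as a score of the authors' test, and the p-value and q-value were deposited for each of 3 pairs of groups. The deposited q-value equalled a Benjamini-Hochberg adjustment over all 34896 tests of the 3 comparisons together, with a largest difference of 5.2e-07. The smallest deposited p-value was 5e-05, shared by 732 tests, and the smallest deposited q-value was 0.00238. The 5 rows marked as having too many fragments are listed at 0 FPKM by the authors and were not interpreted, Col1a1 among them. Spreadsheet conversion had turned 24 symbols into dates, and those rows were not named.

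Log2 folds were computed here as the ratio of the FPKM values deposited by the authors, because the deposited fold columns hold unreadable entries where a group is at 0. The design fixed earlier had named folds with 1 added to both FPKM values. The plain ratio was used instead for ranking and text, since its SE can be taken from the test statistic. The fold with 1 added is given where values near 0 moved it most. The SE is the absolute log2 fold divided by the authors' test statistic. The normal quantile of the deposited p-value was 1.42 times that statistic in the median gene, so this SE is the larger of the 2 that could be used. Its median was 0.334 at 1 h. Over 6678 genes with a mean FPKM of at least 10 it was 0.320, above the standard deviation of their 1 h folds, 0.227. This SE is therefore likely too large there. No fold is given where a group is listed at 0. The median log2 fold of the 10707 genes with an FPKM of at least 1 in a group was −0.00 at 1 h, −0.00 at 24 h and −0.01 for 24 h over 1 h.

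Without replicate values no test between groups was run here. Calls are the authors' significance mark, a q-value of at most 0.05, and the largest p-value called was 0.002. They compare these pools of libraries, and whether the libraries came from separate cell preparations is not given in the sources used here. Named genes followed a rule fixed before the data were examined, but with the plain ratio in place of the fold with 1 added. With 1 added, other genes could stand among the highest or lowest. The rule took the 10 highest and 10 lowest log2 folds per time among called genes with an FPKM of at least 1 in a group. For 24 h over 1 h it took 5 and 5. It added up to 4 called members per gene list or, with none called, the 2 with the highest FPKM, as well as Nr3c1 and the 5 highest GR regions at called genes. Some genes that met this rule are not reported here, though they remain in all counts. Rows sharing their locus with another row (1546) or their symbol with another row (948) are reported as uncertain where named.

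The 21 gene lists were fixed before the data were examined as well. Of their 430 entries 409 had a row, 1 of them by an older symbol from a table of gene names whose assembly is GRCr8, used for names only. Each list was described by its counts of calls, by a Benjamini-Hochberg adjustment over the list alone, and by the median of log2(FPKM + 1) differences. The percentile of that median among 10000 random lists, matched on 10 strata of mean expression, describes these libraries and is not a p-value. Some genes stand on more than 1 list, such as Per1, Pdk4, Klf15 and Fkbp5.

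GR regions came from an integrated sheet whose ChIP experiment belongs to another series. The height of a region is a signal, the authors' highest average tag value, and its log2 ratio of Dex over control was deposited with it. The header of that ratio names the ChIP control as DMSO, not ethanol. The position of a region and its distance to the gene start, in bases, were assigned by the authors as well. Peak caller and normalization are not given in the sources used here, and 6 per-sample ChIP columns were not used. The sheet paired 8514 regions with genes in 11363 rows, 9281 of them with an expression row, so that 5793 genes had both. Shares of called genes with a region carry exact Clopper-Pearson 95% intervals and were set against 10000 random lists of tested genes matched on expression.

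The overlap of the calls at both times was set against independent lists and against 100 simulations of unchanged groups sharing the control. Alternatives were a q-value of at most 0.01, at least a 1.5-fold change, an FPKM of at least 1, adjustment within a comparison, centring on the median gene, a pseudocount of 0.1, regions within 10 kb of the gene start or touching a promoter, regions above the median height and a background of expressed genes. Matching on 5 strata of locus length was chosen after seeing the data. Folds with 1 added, the measure of the design fixed earlier, were set against the plain ratio that replaced them. Cochran's Q set the folds of cell type markers against their weighted mean, with its 95% bound from the chi-squared distribution, also chosen after seeing the data.

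The scripts were tested on simulated data, with normal errors of the size implied by the p-values and adjustment within each comparison alone. The rates describe that simulation and not the power of the authors' calls. Each share of changed genes rests on 55 to 76 genes. For 1 h against control, over 11573 genes, 19.1% of genes changed 1.5-fold, 77.8% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 0.0615% of unchanged genes were called. For 24 h against control, over 11664 genes, the shares were 14.7%, 64.3% and 96.1%, with 0.0349% of unchanged genes called. For 24 h against 1 h, over 11629 genes, they were 9.09%, 79.7% and 97.4%, with 0.0612% of unchanged genes called. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.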

Results

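Gene expression was measured by RNA sequencing in neonatal rat ventricular myocytes, heart muscle cells isolated from the ventricles of newborn Sprague Dawley rats and enriched over a Percoll gradient and by preplating. Cells received ethanol as control or 100 nM dexamethasone (Dex), a synthetic glucocorticoid that activates the glucocorticoid receptor (GR, gene Nr3c1), for 1 h or 24 h. Each of the 3 groups was 1 sample, and the sample titles speak of 2 libraries per group. The same ethanol control served both times, and no treatment time is given for it. Effects of Dex therefore cannot be told apart from those of time in culture. The deposited table held 1 pooled FPKM value per gene and group for 17450 gene rows. FPKM is a count of fragments scaled by transcript length and library size. No replicate values were used here, so no spread between replicates was computed. Whether such a spread entered the authors' test is not given in the sources used here. The errors given are standard errors (SE) of the log2 fold implied by the authors' test statistic. Sequencing depth is unknown. The FPKM sums were 652814 in control, 643628 at 1 h and 658159 at 24 h, with 10473, 10479 and 10483 genes at an FPKM of at least 1. A gene is said to have risen or fallen where the authors' deposited table marks it as significant for that comparison.

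The comparison of 1 h with control asked which transcripts respond early to GR activation in cardiomyocytes. Cldn1, a claudin of tight junctions (gene XLOC_004355, rn5 chromosome 11, 82888891 to 82904046), rose from an FPKM of 0.116 to 1.24. Its log2 fold was 3.42 ± 0.66, and 1.01 with 1 added to both values, the measure of the design fixed earlier. Pdk4, the pyruvate dehydrogenase kinase that restrains glucose oxidation (XLOC_012000; chromosome 4, 30453697 to 30463700), rose from 4.06 to 32.8 FPKM (log2 3.01 ± 0.38). The clock gene Per1 (XLOC_002810; chromosome 10, 55430183 to 55439080) rose by a log2 fold of 2.49 ± 0.32 and Klf15, a transcription factor of cardiac metabolism (XLOC_011726; chromosome 4, 186906049 to 186918645), by 2.13 ± 0.34. Among the transcripts that fell were Dusp5, a phosphatase acting on ERK kinases (XLOC_001211; chromosome 1, 281658074 to 281671486), with a log2 fold of −1.74 ± 0.38, and Cxcr4, the receptor of the chemokine Cxcl12 (XLOC_005220; chromosome 13, 50394127 to 50398032), with −1.52 ± 0.36.

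Of 11582 genes tested at 1 h, 100 were called (0.863%), 72 higher and 28 lower. Of these, 45 rose and 15 fell at least 2-fold. At a q-value of at most 0.01, 49 were higher and 14 lower, and adjustment within the 1 h comparison alone gave the same counts. The median log2 fold was 1.19 among the genes called higher and −1.07 among those called lower. The other genes with the highest folds were Arrdc3, an arrestin-domain protein (2.56 ± 0.36), Abra, an actin-binding protein of muscle (2.40 ± 0.36), the transcription factor Sox8 (2.36 ± 0.58; 0.80 with 1 added), Fam46b (2.15 ± 0.36), the adhesion receptor Flrt3 (2.11 ± 0.41) and Arrdc2 (from 2.69 to 10.7 FPKM). Below control were also Phlda1 (−1.46 ± 0.33), the cartilage collagen Col2a1 (−1.43 ± 0.43), Socs3, an inhibitor of cytokine signalling (−1.42 ± 0.51), the cytokine Lif (−1.36 ± 0.51), the kinase Plk2 (−1.33 ± 0.31) and Hes1, a transcriptional repressor downstream of Notch (−1.16 ± 0.33). A pair of Rn5-8s ribosomal RNA rows fell as well (−1.85 ± 0.46 and −1.46 ± 0.44), but this RNA stands on 6 rows of near-identical copies, and its values are uncertain. In the authors' deposited table the smallest q was 0.00238, reached by Cldn1, Pdk4, Per1, Dusp5 and Cxcr4, and q was 0.0191 for Socs3.

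Of the 31 tested members of a list of classical GR targets, 17 rose at 1 h, none fell and 14 were not called. The median log2 difference of the list was 0.67, above all 10000 random lists of equal size and expression. List medians here and below are over members with usable values, tested or not, 34 in this list. Adjusted over the list alone, 22 members rose. Sgk1, a kinase regulating ion transport, rose from 8.89 to 34.3 FPKM (log2 1.95 ± 0.33), and Nfkbia, the inhibitor of NF-kB, rose by 1.74 ± 0.33. The GR co-chaperone Fkbp5 rose by 0.90 ± 0.33, the call of 1 member among 15 of the list of GR and mineralocorticoid receptor signalling and chaperones (median −0.02, percentile 33.6). Nr3c1 itself had 19.7 FPKM in control and 19.6 at 1 h and was not called. Its locus holds 4 rows, so its value is uncertain. Beside these targets, globin transcripts of red blood cells also rose at 1 h. Hba1 went from 48.2 to 97.5 FPKM (log2 1.02 ± 0.37), Hba2 rose by 0.97 ± 0.38 and Hbb-b1 by 1.10 ± 0.44, all 3 tested members of the erythroid list. The median over its 6 members was 0.56, above all random lists, and 1.00 over the 3 with an FPKM of at least 1. Hba1 and Hba2 are near-identical paralogs, and the split between them is uncertain.

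Immediate early genes and inflammatory genes held most of the list members that fell at 1 h. Of 24 immediate early genes, Ier3 (−1.14 ± 0.32), Junb (−0.76 ± 0.32) and Egr1 (−0.71 ± 0.32) fell and 21 were not called (median −0.05, percentile 10.4). Of 17 tested cytokines, chemokines and NF-kB targets, Lif and the transcription factor Irf1 (−0.80 ± 0.36) fell, while Ptgs2, the inducible cyclooxygenase, rose (1.42 ± 0.37), and the median over 25 members, −0.05, stood at percentile 1.59 (−0.12 over the 14 with an FPKM of at least 1). In the list of muscle atrophy and autophagy genes, Klf15 rose with Ddit4 (0.70 ± 0.32) and Sesn1 (1.97 ± 0.33), which inhibit mTOR signalling, and 14 were not called (median 0.05, percentile 87.2). Sesn1 shares its locus with another row and is uncertain. In glucose metabolism and insulin signalling, Pfkfb3, a regulator of glycolysis, rose (1.57 ± 0.34) and the insulin receptor substrate Irs1 fell (−0.79 ± 0.33), with 18 not called (median −0.06, percentile 9.24). Pdk4 was the 1 called member among 28 tested fatty acid metabolism genes (median −0.00, percentile 47.5) and Per1 among 13 circadian genes (median 0.00, percentile 51.7). Of 19 tested vasoactive and adrenergic genes 1 rose and 18 were not called (median −0.01, percentile 34.8).

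In the remaining lists no member was called at 1 h. The number of members with an unadjusted p under 0.05 in the authors' deposited table was 2 for the apoptosis list, 1 each for the fetal, calcium, endothelial and cell cycle lists, and 0 for the other 6. The median of the 22 fetal and hypertrophic cardiac genes, −0.09, stood at percentile 1.62. Nppa, the atrial natriuretic peptide, had 8985 FPKM in control and 8959.9 at 1 h, and the cardiac actin Actc1 had 5592 and 4935. For 17 sarcomere and Z-disc genes the median was −0.03 (percentile 38.0), with Myl2, a myosin light chain, at 8776 and 8731 FPKM and the tropomyosin Tpm1 at 2771 and 2720.1. For 22 calcium and ion handling genes, 21 of them tested, it was −0.04 (percentile 16.7), with the calcium pump Atp2a2 at 463 and 468 FPKM. For 22 genes of oxidative phosphorylation and the TCA cycle it was −0.02 (percentile 48.6). For 20 interferon response genes it was 0.07 (percentile 95.2), for 22 cell cycle genes 0.01 (percentile 68.3), and for 16 apoptosis and survival genes 0.12 (percentile 99.1), where 1 gene rose when adjusted over the list alone.

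Among markers of other cell types at 1 h, the median was −0.02 (percentile 45.7) for 20 extracellular matrix and fibroblast genes, with the intermediate filament Vim at 2296 FPKM in control and 2268 at 1 h. It was 0.02 (percentile 67.8) for 15 endothelial genes, with the TGF-beta co-receptor Eng at 107 and 103 FPKM. For 16 macrophage and leukocyte genes, 15 of them tested, it was 0.11 (percentile 98.7), with lysozyme, Lyz2, at 78.2 and 79.7 FPKM. For 12 smooth muscle and pericyte genes the median was −0.18, below all random lists, with the actin Acta2 at 4806 and 4142 FPKM and the calponin-related Tagln at 3491 and 3045. For the lists other than the GR targets and the apoptosis genes, the counts adjusted over the list alone equalled those over all genes tested.

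The comparison of 24 h with control asked which transcripts differ after sustained exposure. Hif3a, a hypoxia-inducible factor subunit (XLOC_001476; chromosome 1, 80223833 to 80245130), rose from 0.0534 to 12.5 FPKM, a log2 fold of 7.87 ± 0.93. Ace, the angiotensin-converting enzyme (XLOC_003122; chromosome 10, 93922061 to 93939118), rose from 1.35 to 41.6 FPKM (log2 4.95 ± 0.38), and Zbtb16, a zinc finger transcription factor (XLOC_015963; chromosome 8, 51578464 to 51739786), from 0.613 to 21.1 FPKM (5.10 ± 0.46). Myl2, the ventricular regulatory myosin light chain, fell from 8776 to 2456 FPKM (−1.84 ± 0.30).

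At 24 h, 726 of 11673 tested genes were called (6.22%), 488 higher and 238 lower, and 339 rose and 168 fell at least 2-fold. At a q-value of at most 0.01, 142 were lower. The median log2 fold was 1.28 among genes called higher and −1.21 among those called lower. Other genes with the highest folds were Sult1a1, a sulfotransferase (6.63 ± 0.89), the claudins Cldn2 (6.44 ± 0.94) and Cldn1 (5.32 ± 0.63), Mlxipl, a carbohydrate-responsive transcription factor (5.76 ± 0.65), Cd163, the haemoglobin scavenger receptor of macrophages (5.59 ± 0.72), Tnfrsf17 (5.31 ± 0.67) and the sorting receptor Sorcs1 (4.86 ± 0.47). Among the lowest were LOC688553 (−5.20 ± 0.85), the retinoid receptor Rxrg (−4.18 ± 0.90), Dhrs7c, an enzyme of the sarcoplasmic reticulum (−4.10 ± 0.64), the lectin Reg3b (−3.74 ± 0.48), Nlrp10 (−3.22 ± 0.70), Asb14 (−3.12 ± 0.71), Cytip (−3.05 ± 0.58), the cartilage protein Lect1 (−2.90 ± 0.65) and Mmp12, the macrophage elastase (−2.84 ± 0.42). Several of these genes lay near 0 FPKM in control or at 24 h, which inflates a plain ratio. With 1 added to both FPKM values the log2 fold was 3.68 for Hif3a, 3.53 for Sult1a1, 2.68 for Mlxipl, 2.34 for Cldn1, 2.07 for Cldn2, and 1.77 for Cd163. It was −2.37 for LOC688553, −1.11 for Rxrg, −2.43 for Dhrs7c, −1.57 for Cytip, −1.46 for Lect1, −1.03 for Asb14 and −0.93 for Nlrp10. In the authors' deposited table q was 0.0423 for Hif3a and 0.00238 for Ace and Myl2.

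**Figure D1:**
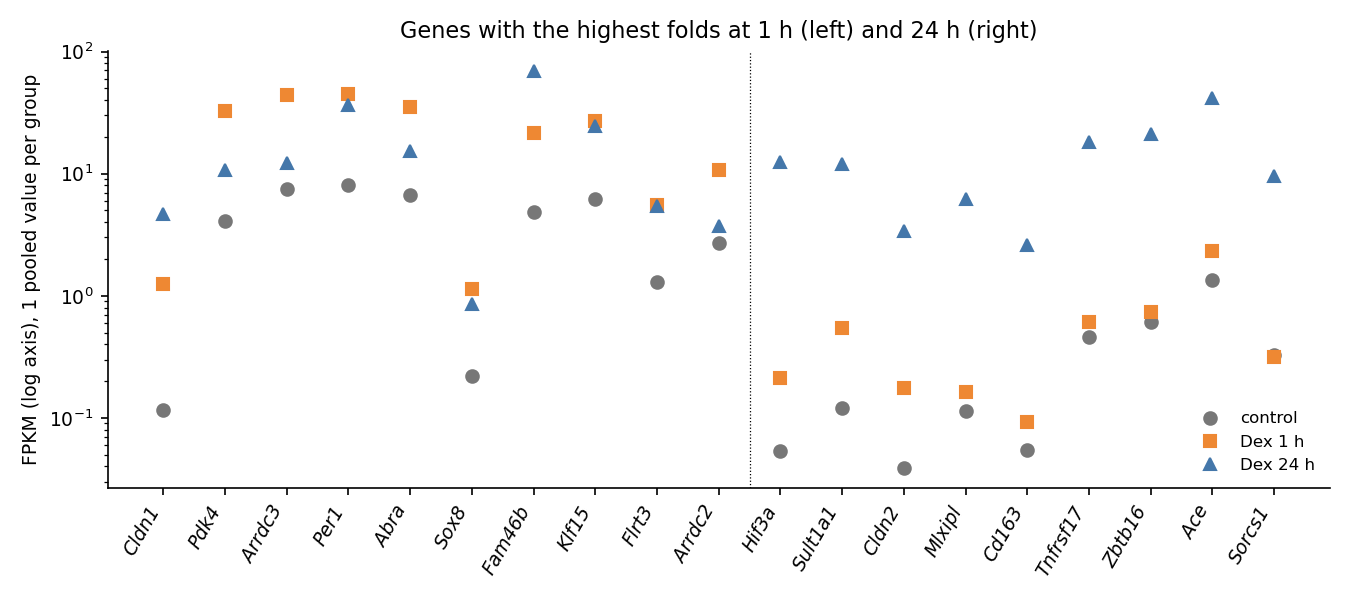
FPKM on a log axis, 1 pooled value per group, for the 10 genes with the highest log2 folds among those called at 1 h (left of the dotted line) and for those of 24 h (right; Cldn1 ranked in both and stands on the left), with control as circles, 1 h as squares and 24 h as triangles. Arrdc3 stood at 44.4 FPKM at 1 h and 12.3 at 24 h, while Zbtb16 stood at 0.732 and 21.1.

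Of 32 tested classical GR targets 21 rose at 24 h, none fell and 11 were not called (median 0.86, above all random lists), and 24 rose when adjusted over the list alone. After Hif3a and Zbtb16, the members with the highest folds were Lcn2, a secreted iron-siderophore binder (4.05 ± 0.46), and the cell cycle inhibitor Cdkn1c (2.79 ± 0.36). In GR and mineralocorticoid receptor signalling, Fkbp5 rose (2.69 ± 0.32), Hsd11b1, which regenerates active glucocorticoid, rose (1.25 ± 0.34) and the mineralocorticoid receptor Nr3c2 fell (−1.20 ± 0.40), with 12 not called (median −0.07, percentile 10.2). Nr3c1 had 13.3 FPKM at 24 h (−0.56 ± 0.45) and was not called.

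None of 22 fetal and hypertrophic genes was called at 24 h, and 3 had an unadjusted p under 0.05 in the authors' deposited table (median 0.07, percentile 89.4). Nppa had 9749 FPKM (0.12 ± 0.32) and Actc1 6125 (0.13 ± 0.32). Among 17 sarcomere and Z-disc genes, Myl2 fell while the intermediate filament Des (1.42 ± 0.31) and the Z-disc protein Myoz2 (0.68 ± 0.31) rose and 14 were not called (median 0.06, percentile 81.9), 3 rising and 1 falling when adjusted over the list alone. Among 21 tested calcium and ion handling genes 5 fell, 1 rose and 15 were not called (median −0.07, percentile 9.21), 7 and 1 when adjusted over the list alone. Those that fell included the potassium channel genes Kcnd2 (−3.49 ± 0.76) and Kcnip2 (−1.61 ± 0.47) and the pacemaker channel Hcn4 (−1.64 ± 0.38), while Kcne1, a potassium channel accessory subunit, rose from 0.603 to 15.9 FPKM (4.72 ± 0.73). The symbol Kcnip2 stands on 2 rows, so its value is uncertain. In the atrophy and autophagy list Klf15 (1.99 ± 0.34), Sesn1 (1.28 ± 0.33) and Foxo3 (0.92 ± 0.33) rose and 14 were not called (median 0.34, above all random lists), and 4 rose when adjusted over the list alone.

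The interferon response list had the lowest median at 24 h. Of 20 tested members 8 fell, none rose and 12 were not called, and 12 fell when adjusted over the list alone. The median of −0.53 lay below all random lists. Mx2, an antiviral GTPase, fell from 10.9 to 2.40 FPKM (−2.18 ± 0.40), and so did Mx1 (−1.64 ± 0.56), the ubiquitin-like modifier Isg15 (−1.38 ± 0.45) and the Isg15 protease Usp18 (−1.32 ± 0.40). Among 17 tested cytokines and NF-kB targets, Ptgs2 (1.65 ± 0.37) and Ccl20 (1.54 ± 0.54) rose, none fell and 15 were not called (median 0.05, percentile 95.2). Adjusted over the list alone, 4 rose. Over the 14 members with an FPKM of at least 1 the median was 0.18 (percentile 98.4). Of 24 immediate early genes Klf2 (0.86 ± 0.34), Zfp36 (0.76 ± 0.31), Btg2 (0.72 ± 0.32) and Klf6 (0.72 ± 0.31) rose and 20 were not called (median 0.14, above the random range of −0.10 to 0.12; 5 when adjusted over the list alone).

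Markers of other cell types moved at 24 h beside these groups. Of 15 endothelial markers 7 rose, none fell and 8 were not called (median 0.52, above all random lists), and 9 rose when adjusted over the list alone. The mucin Emcn rose by 2.10 ± 0.44, the VEGF receptor Kdr by 1.85 ± 0.35 and the adhesion molecule Pecam1 from 9.33 to 26.7 FPKM (1.52 ± 0.34). Of 16 macrophage and leukocyte markers 5 rose, 1 fell and 10 were not called (median 0.00, percentile 55.4), 6 and 3 when adjusted over the list alone. The complement genes C1qc (3.34 ± 0.44) and C1qb (2.82 ± 0.42) rose with Cd163, whereas Emr1, the macrophage antigen F4/80, fell (−1.85 ± 0.54). The globins remained higher, with Hba1 at 103 FPKM (1.09 ± 0.35), and 3 of 4 tested erythroid genes rose (median 0.63 over 6 members and 1.08 over the 3 with an FPKM of at least 1; 4 when adjusted over the list alone). Among 12 smooth muscle and pericyte genes Abcc9 (0.95 ± 0.32) and Lmod1 (0.81 ± 0.31) rose and Rgs5 fell (−1.43 ± 0.43) and 9 were not called, with a median of 0.19 at percentile 98.4, and 3 rose and 1 fell when adjusted over the list alone. In the matrix and fibroblast list the transcription factor Tcf21 rose (0.87 ± 0.32) and 19 were not called (median 0.05, percentile 78.0).

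Metabolic, clock, cell cycle, vasoactive and survival genes form the remaining lists. Of 28 tested fatty acid metabolism genes 4 rose, among them the lipase Pnpla2 (1.48 ± 0.32), Pdk4 (1.40 ± 0.40) and the lipoprotein lipase Lpl (0.80 ± 0.31), Fabp3, a fatty acid carrier, fell (−1.18 ± 0.32), and 23 were not called (median −0.07, percentile 5.67). The symbol Pnpla2 and the locus of Fabp3 each stand on 2 rows, so both are uncertain. In glucose metabolism the glucose transporter Slc2a1 (1.43 ± 0.31) and Pfkfb3 (1.30 ± 0.35) rose and 18 were not called (median 0.01, percentile 58.4), 3 rising and 1 falling when adjusted over the list alone. Of 13 circadian genes Per1 (2.19 ± 0.32) and Arntl (0.82 ± 0.32) rose while Per3 (−1.99 ± 0.38), Dbp (−1.36 ± 0.42) and Tef fell and 8 were not called (median −0.32, percentile 0.01). Of 22 cell cycle genes the replication licensing gene Mcm5 fell (−0.81 ± 0.32), 21 were not called, and 6 fell when adjusted over the list alone. The median of −0.32 lay below all random lists. None of 22 oxidative phosphorylation genes was called and 1 had an unadjusted p under 0.05 in the authors' deposited table (median −0.10, percentile 2.25; Atp5b 1858 and 1671 FPKM). In vasoactive signalling Ace, the cyclooxygenase Ptgs1 (2.25 ± 0.35), Adm (1.14 ± 0.33) and the angiotensin receptor Agtr1a (1.12 ± 0.42) rose and 15 were not called (median 0.09, percentile 93.3), with 6 rising and 2 falling when adjusted over the list alone. The anti-apoptotic Bcl2l1 rose (0.89 ± 0.31), the 1 call among 16 apoptosis and survival genes (median 0.31, above all random lists; 2 when adjusted over the list alone). Of the 42 list medians, 18 lay outside the central 95% of random lists, 7 at 1 h and 11 at 24 h. In the lists of receptor signalling, fetal, matrix, fatty acid, circadian and oxidative phosphorylation genes the count adjusted over the list alone equalled that over all genes tested.

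**Figure D2:**
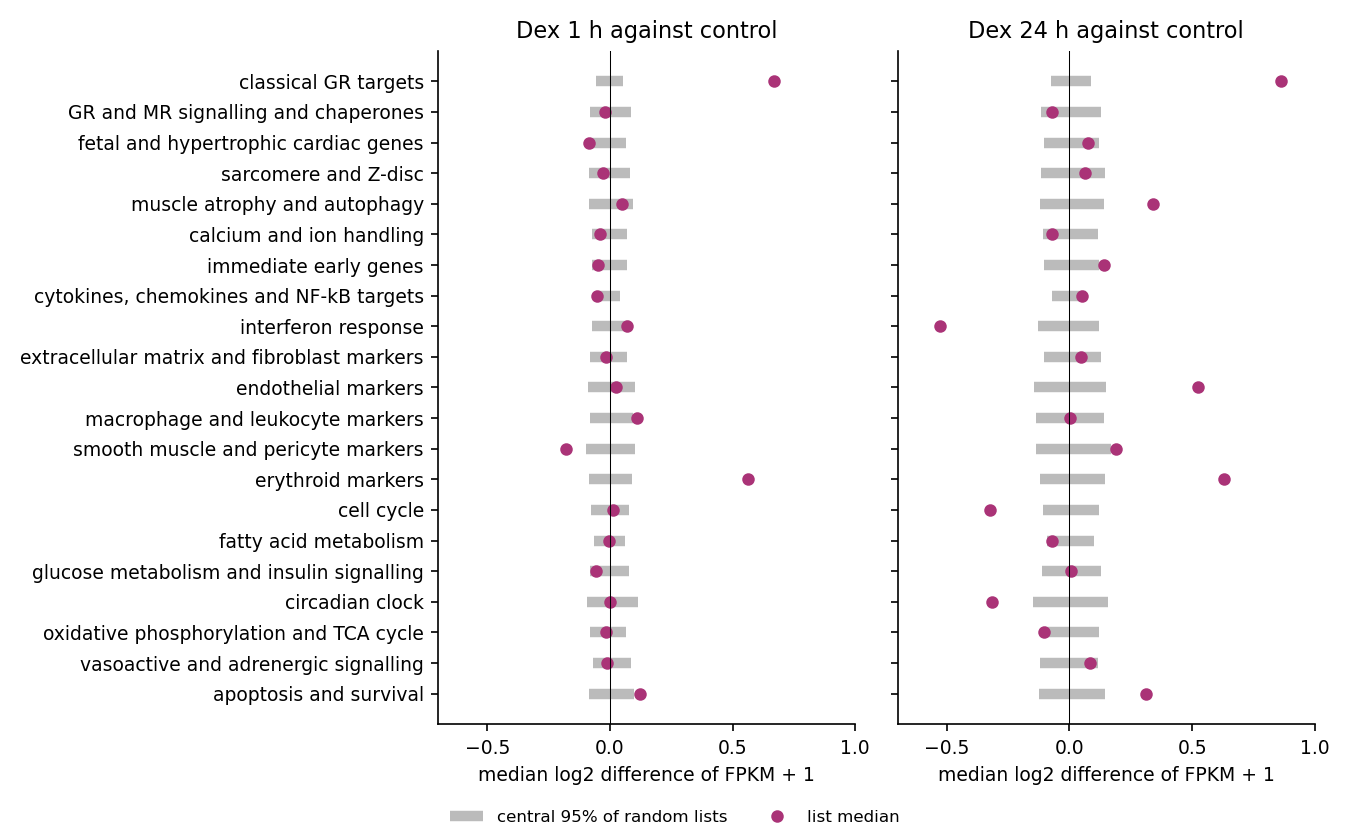
Median log2 difference of FPKM with 1 added, for each of the 21 gene lists (rows) at 1 h (left) and 24 h (right) against control; points are list medians and grey bars the central 95% of 10000 random lists matched on expression. The classical GR targets lie at 0.67 and 0.86, and the interferon response list lies at −0.53 at 24 h.

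The direct comparison of 24 h with 1 h asked which transcripts differ between the times. The highest folds among called genes were those of Hif3a (5.87 ± 0.59), Orm1, an acute phase plasma protein (5.56 ± 0.45), Kcne1 (5.48 ± 0.85), Mlxipl (5.24 ± 0.59) and Sorcs1 (4.92 ± 0.47). Among the lowest were those of LOC688553 (−5.24 ± 0.85), Rxrg (−3.93 ± 0.91), Dhrs7c (−3.77 ± 0.65) and Reg3b (−3.64 ± 0.48). With 1 added the fold was 3.48 for Hif3a, 5.05 for Orm1, 3.64 for Kcne1, 2.62 for Mlxipl and 3.01 for Sorcs1. It was −2.40 for LOC688553, −0.97 for Rxrg, −2.14 for Dhrs7c and −3.12 for Reg3b. Orm1 stood at 0.0256 FPKM in control, 2.31 at 1 h and 109 at 24 h, yet was not called against control (q = 0.99958 at both times in the authors' deposited table). Of 11641 tested genes 573 were called (4.92%), 385 higher and 188 lower at 24 h, with median log2 folds of 1.25 and −1.28. At a q-value of at most 0.01, 108 were lower.

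Of the 72 genes higher at 1 h, 50 were also called higher at 24 h, where independent lists would share 2.84 of the 11545 genes tested at both times. Of the 28 lower at 1 h, 7 were also called lower at 24 h, against 0.577 for independent lists. Of the 22 genes higher at 1 h and not called at 24 h, 7 differed between the times and 15 did not, and of the 21 such lower genes 10 differed and 11 did not. No gene was called in opposite directions. Pdk4 (−1.62 ± 0.35), Arrdc3 (−1.85 ± 0.35), Arrdc2 (−1.52 ± 0.37) and Abra (−1.21 ± 0.34) were lower at 24 h than at 1 h, and Cldn1 (1.90 ± 0.41) and Fam46b (1.69 ± 0.32) higher. Of the genes that had fallen at 1 h, Cxcr4 (1.54 ± 0.36), Phlda1 (0.98 ± 0.33), Dusp5 (0.93 ± 0.39) and Hes1 (0.91 ± 0.34) were higher at 24 h than at 1 h, and Cxcr4 stood at 19.4 FPKM against 19.2 in control. Among genes tested at both times, 406 were called higher at 24 h and not at 1 h, of which 278 differed between the times, as did 157 of the 231 called lower at 24 h alone.

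Both comparisons share the control pool, so part of this overlap may come from it. Over 6678 genes with a mean FPKM of at least 10, 37 calls were shared in direction, whereas 100 simulations of unchanged groups gave a mean of 0.64 and at most 3. All simulated genes were unchanged at both times. The simulations therefore do not bound the part of the shared control among genes that changed at 24 h. Across genes, which are not independent replicates, the covariance of the log2 folds was 0.0546. Simulated unchanged groups gave 0.0317 with errors implied by the p-values and 0.0653 with errors implied by the test statistics. The observed covariance lay 0.0230 above the former and 0.0107 below the latter. Errors implied by the test statistics had a median of 0.320, above the standard deviation of all 1 h folds, 0.227. They are therefore too large for unchanged genes here. Those implied by the p-values had a median of 0.225, close to that standard deviation, and the excess of 0.0230 depends on them. The correlation across genes was 0.592, against 0.497 and 0.503 in the simulations.

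**Figure D3:**
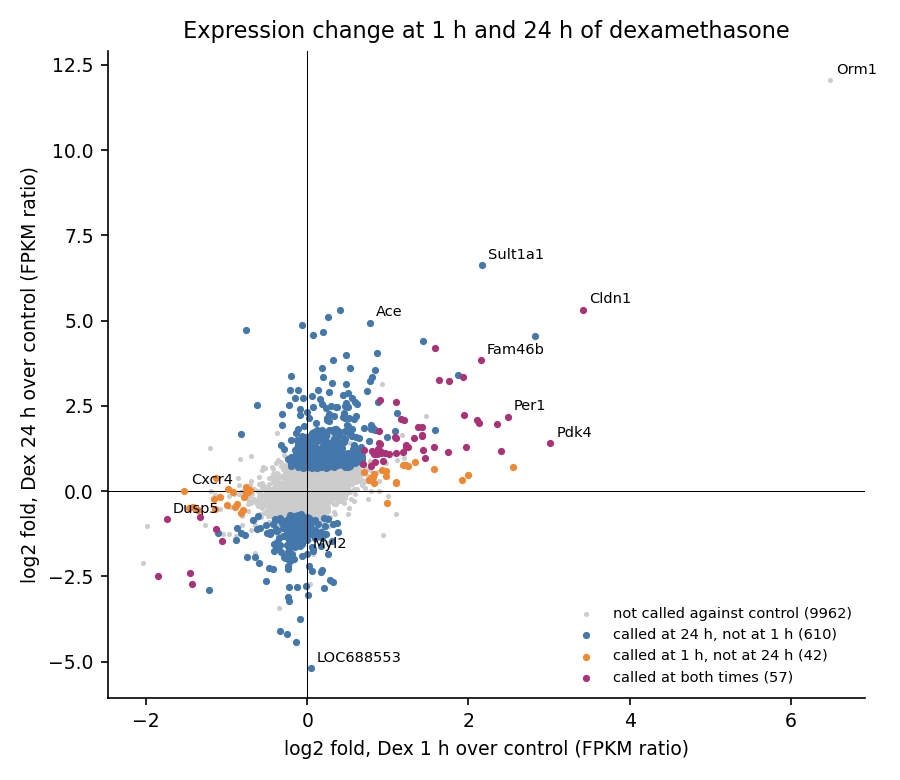
Log2 fold of FPKM at 1 h (horizontal) against 24 h (vertical), each over control, for 10671 genes tested at both times with an FPKM of at least 1 in a group; colours mark genes called at both times (57), at 1 h alone (42), at 24 h alone (610) or at neither (9962). Pdk4 lies at 3.01 and 1.40 and Orm1, not called against control, at 6.49 and 12.05.

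GR binding regions of such cells, deposited in an integrated table from a chromatin immunoprecipitation experiment of another series, were set beside the expression calls to ask how often responding genes carry a GR region. The highest regions at called genes lay in the gene Zbtb16 (rn5 chromosome 8, 51664392 to 51665056), upstream of Crispld2, a secreted protein gene (chromosome 19, 63403871 to 63404472), in Sesn1 (chromosome 20, 48418455 to 48418930), downstream of the tissue factor gene F3 (chromosome 2, 243360880 to 243362058) and upstream of the transcription factor gene Klf9 (chromosome 1, 248187677 to 248189183). Their heights in the authors' own units were 126, 122, 118, 118 and 112, where the median region had 20.9. Crispld2 rose at 24 h (2.30 ± 0.31), and F3 (1.22 ± 0.33) and Klf9 (1.32 ± 0.32) rose at 1 h. Zbtb16 carried 15 regions, Per1 3 and Fkbp5 6, whereas Ace, Cldn1 and Cldn2 had 0. Regions paired with a gene lay at most 10401 bases upstream of its start. A gene without a region here may therefore have one farther away.

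Of the 72 genes called higher at 1 h, 51 had a GR region (70.8%, exact 95% interval 58.9 to 81.0), where expression-matched random lists had 46.1% (central range 34.7 to 56.9). Of the 488 called higher at 24 h, 269 had a region (55.1%, 50.6 to 59.6), against 42.5% in random lists (38.3 to 46.7). Of the 238 called lower at 24 h, 66 had a region (27.7%, 22.1 to 33.9), below the 40.1% of random lists (34.0 to 46.2). The 17 of 28 genes called lower at 1 h (60.7%, 40.6 to 78.5) stood inside the random range of 28.6 to 64.3. With regions above the median height the excess over random lists was 21.4 percentage points for genes higher at 24 h, −6.74 for those lower at 24 h and −1.92 for those lower at 1 h. With regions within 10 kb of the gene start or touching a promoter it was 7.07 points for genes higher at 24 h. With random lists matched on locus length too, chosen after seeing the data, the share of genes lower at 1 h lay 19.7 percentage points above random lists and outside their range. The highest region per gene had a median height of 38.2 among bound genes higher at 1 h and 32.7 at 24 h, against 21.8 and 21.6 among bound genes not called. The former had a median of 2 regions per gene and the latter 1, and a highest value rises with the number of regions. Of the 8514 regions 8459 were higher with Dex than in the ChIP control in the authors' deposited table, with a median log2 ratio of 2.42. That control is named DMSO, whereas the RNA control was ethanol. Of the region and gene pairs, 53.6% placed the region inside the gene. The intervals cover sampling of genes only, and the ChIP treatment time and replicates are not given in the sources used here.

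**Figure D4:**
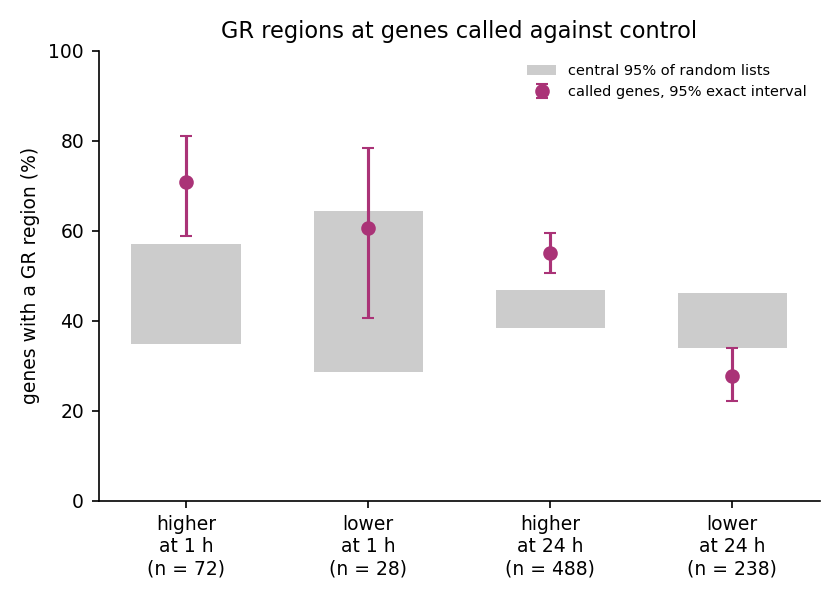
Percent of genes with at least 1 GR region among genes called higher or lower at 1 h and 24 h against control; points with bars are the share and its exact 95% interval, and grey boxes the central 95% of 10000 random lists matched on expression. The share was 70.8% for genes higher at 1 h and 27.7% for genes lower at 24 h.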

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

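No test in this part was chosen after its result was seen. Each result below stands here because expression at 24 h differed from that at 1 h in the authors' own test of 24 h against 1 h. That test does not separate Dex from time in culture.

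By that test 385 genes were higher and 188 lower at 24 h than at 1 h. Of the genes higher at 1 h against control 21 differed between the times, and of those lower at 1 h 12 did. Among early genes that rose, the log2 fold of 24 h over 1 h was 1.90 for Cldn1 and 1.69 for Fam46b, which went further up. It was −1.62 for Pdk4, −1.85 for Arrdc3, −1.21 for Abra and −1.52 for Arrdc2, which fell back. Among early genes that fell, it was 0.93 for Dusp5, 1.54 for Cxcr4, 0.98 for Phlda1 and 0.91 for Hes1, and −1.30 for Col2a1, which fell further.

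Among the genes with the highest folds at 24 h, the log2 fold over 1 h was 5.87 for Hif3a, 5.56 for Orm1, 5.48 for Kcne1, 5.24 for Mlxipl, 4.92 for Sorcs1, 4.91 for Tnfrsf17 and 4.85 for Zbtb16. For Cd163 it was 4.81, for Sult1a1 4.47, for Cldn2 4.27 and for Ace 4.17. Among the lowest it was −5.24 for LOC688553, −3.93 for Rxrg, −3.77 for Dhrs7c, −3.64 for Reg3b, −3.05 for Mmp12 and −3.05 for Cytip. For Nlrp10 it was −2.99, for Asb14 −2.88 and for Lect1 −1.67. These are plain ratios, which values near 0 FPKM inflate. With 1 added, the measure of the design fixed earlier, the fold was −0.81 for Nlrp10, −0.90 for Asb14, −0.67 for Lect1 and −0.97 for Rxrg. It was 1.72 for Cd163 and 1.90 for Cldn2. A further 54 of 390 gene list members differed between the times, 32 higher and 22 lower at 24 h. Among them were Myl2 (−1.83), Des (1.35), Mx2 (−2.21) and Emcn (1.86).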

How the results depend on the processing

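Matching on locus length was chosen after the results were seen. The other alternatives were fixed before, folds with 1 added being the planned measure that the plain ratio replaced. Centring is left out of the counts below, since it cannot change a call or the place of a list among random lists. Of 24 counts of calls under alternatives, 20 stayed within 1.5 times the reported count. Among these are the 6 counts with at least a 1.5-fold change, a filter that removed no called gene and so says nothing of stability. At a q-value of at most 0.01 the genes lower at 1 h went from 28 to 14, those lower at 24 h from 238 to 142 and those lower at 24 h than at 1 h from 188 to 108, as a stricter threshold calls fewer genes. With adjustment within the comparison alone, the genes lower at 1 h were also 14. Those higher at 1 h went from 72 to 49, so 63 of the 100 calls at 1 h remained. The others rest on adjustment together with the other comparisons. At 24 h the same change raised the calls from 726 to 790. The 4 alternatives of the overlap stayed within 1.5 times, and at a q-value of at most 0.01 it held 35 higher and 5 lower genes. Of 84 list medians under alternatives, 83 kept their side of the central range of random lists. The exception was the cytokine list at 24 h among members with an FPKM of at least 1, whose median of 0.18 passed it at percentile 98.4, and the cause was not tested. Of 16 shares of genes with a GR region, 15 kept their side of the random range, though their size varied with the choice of regions. The exception was genes lower at 1 h with lists matched on locus length too, 19.7 percentage points above random, and the cause was not tested. With 1 added, 28 of 50 named folds left their 95% interval and 25 became over 1.5 times smaller. No paired analysis was possible because the files give 1 pooled value per group, and for the same reason no replicate could be left out in turn. Depth is unknown. Genes near 0 FPKM in control limit the calls at 24 h, where 6 of 11 genes at least 8-fold higher with a control FPKM under 0.1 were not called, against 3 of 34 with a higher control value.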

Other observations

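The genes of the first 2 paragraphs, and the tests of this part other than the GR region excess over lists matched on expression, were chosen after the values were seen. These genes stand outside the fixed lists, were picked by hand and represent no tested group. Mb, myoglobin, the oxygen store of muscle (rn5 chromosome 7, 118094390 to 118101622), fell from 274 to 38.7 FPKM (log2 −2.82 ± 0.32). The muscle creatine kinase Ckm fell from 152 to 43.9 (−1.79 ± 0.31), the muscle phosphoglycerate mutase Pgam2 from 14.6 to 3.03 (−2.27 ± 0.46), Hrc, a calcium-binding protein of the sarcoplasmic reticulum, from 18.2 to 3.72 (−2.29 ± 0.36) and the M-band protein Myom2 from 92.2 to 43.8 (−1.07 ± 0.31). The mitochondrial creatine kinase Ckmt2 rose instead, from 5.01 to 39.5 (2.98 ± 0.38). At 1 h the gap junction gene Gja1 fell from 127 to 71.6 FPKM (−0.82 ± 0.31), and at 24 h another gap junction gene, Gja5, rose from 22.8 to 69.9 (1.62 ± 0.32).

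Timp3, a metalloproteinase inhibitor, rose from 92.8 to 518 FPKM (2.48 ± 0.31; its locus overlaps another row, so it is uncertain), the matricellular protein Nov from 155 to 640.1 (2.05 ± 0.31), the heparan sulfatase Sulf2 from 39.0 to 197 (2.33 ± 0.30) and the lectin Lgals3 from 129 to 381 (1.56 ± 0.31). The neuropeptide gene Gal rose from 0.687 to 17.5 FPKM (4.67 ± 0.62) and Xdh, xanthine dehydrogenase, from 1.16 to 18.5. Th, the rate-limiting enzyme of catecholamine synthesis, had 0.0254 FPKM in control and 5.27 at 24 h and was not called, with p = 0.06335 in the authors' deposited table.

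Globin transcripts were higher in both Dex pools. All 4 rows with an alpha or beta globin symbol were called at both times, with log2 folds between 0.97 and 1.18. The most abundant, Hba1, went from 48.2 to 97.5 and 103 FPKM. A larger share of red blood cell RNA in both Dex pools predicts a common fold. The range of these folds was 0.22, less than their median SE of 0.37, so a difference in carried-over blood cells may account for it. Both times share the control pool, and induction of the globins by a common fold would give the same narrow range. The range therefore does not decide between these causes. Induction through GR stays open, since 0 of the 4 rows had a GR region, which does not exclude a distant region or an indirect effect.

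Endothelial and macrophage markers moved at 24 h in cells that Percoll and preplating had enriched for myocytes. A changed share of macrophages alone predicts a common fold. Cochran's Q of the folds of the 8 markers with low control values, those under an FPKM of 1 left out, was 129. Its 95% bound was 14.1, and 7 markers lay more than 2 SE from their weighted mean. This argues against a single common change of share as the whole cause. The markers had been seen to move apart before Q was computed, so Q gives the size of that spread and is no independent support. The list holds leukocyte as well as macrophage markers, so Q does not cover separate changes of share among these cells. A change of expression within macrophages stays open as a hypothesis and was not tested. For a larger share of endothelial cells Q was 40.7 over 14 markers (bound 22.4) and 16.7 over the 7 with low control values (bound 12.6), but the fold of Emcn less 2 SE exceeded the lowest fold plus 2 SE by 0.30 and 0.03, both below the median SE of 0.34 and 0.41. A larger share and induced expression cannot be told apart here, since expression of a marker in other cells of the culture could dilute its fold.

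GR regions were more frequent at genes called higher, and features of those genes other than their response could give such an excess. The excess over random lists matched on expression was 24.8 percentage points at 1 h and 12.6 at 24 h, both outside the random range, and at 24 h it was 7.07 with regions near the gene start or touching a promoter and 21.4 with regions above the median height. This argues against expression level as the whole cause. Matched on locus length too, it was 29.5 and 11.9 points, again outside the range, which argues against length. That the genes respond to GR bound nearby is a hypothesis here, and chromatin accessibility was not tested.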
